A study of Lactobacillus delbrueckii subsp. bulgaricus with 3 samples.

How the data were processed

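Single cells of *Lactobacillus delbrueckii* subsp. *bulgaricus* sp1.1 were profiled in 3 libraries: a culture (CT), a freeze-dried powder (FD) and the powder after 2 weeks of cold storage (FD2w), with 1 library per group. Groups were taken from the library names in the labels. Per the labels' protocols, cells were fixed and permeabilized, RNA was reverse transcribed inside the cells with random primers, cells were barcoded in droplets on a commercial bacterial single-cell platform, and libraries were sequenced as pairs of 150-base reads. The labels name the molecule as polyadenylated RNA, which differs from the random priming in the protocol and was left as it is. The aligner, genome build, annotation, counting and cell-calling rules are not given in the sources used here.

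The deposited values are whole-number counts per feature and cell barcode, with no normalization by the authors visible in them. Whether molecular identifiers were collapsed is not stated, so they are called counts here, and intervals of CPM and ratios cover counting error only. The barcodes are those the authors deposited, and no further filter on cells was applied unless stated. No doublet caller was run, and results were recomputed without the 5% of cells with the most counts in each library.

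The matrix of 3805 barcodes and 2025 features was recorded under the FD2w sample, whose lists hold 17002 barcodes and 2176 features, and the matrix of 17002 barcodes was recorded under the FD sample. Each matrix was assigned to the sample whose barcode and feature lists have its sizes, and the exchange was run as an alternative. Which powder each library came from rests on those lists.

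The CT and FD tables have the same 2025 gene features. The FD2w table has these and 151 more: 27 rRNA, 94 tRNA and 30 features named nc. The features gene45 to gene48 held most counts of CT and FD and almost none in FD2w, while their neighbours gene44 and gene49 were near 0 in all 3, so they were treated as ribosomal RNA. This was decided after the values were seen, from counts and position, since the files name no product. CPM were computed per 1000000 counts on the 2021 other shared gene features. Symbols come from the feature tables: 1305 of 2025 genes have one, 127 symbols are on several genes and 21 genes are named *dppA*. Symbols borrowed from other organisms were printed as given, with the gene number. Coordinates and products were not used here, since the files hold none.

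For each gene the counts of a library were summed over cells and given as CPM with an exact Poisson 95% interval. The ratio of 2 libraries has an exact conditional binomial (Clopper-Pearson) 95% interval, and a ratio against 0 counts uses a floor of 3 counts. A gene counted as measured with at least 100 counts over the 2 libraries, and as higher or lower with a ratio of at least 2 or at most 0.5 and an interval excluding 1. This is a description of size in 2 libraries, not a test of conditions. Named genes, by a rule set before the data were examined, are the 12 largest and 12 smallest ratios per comparison among genes with a symbol, the 3 most extreme measured members of each gene list, the 5 highest CPM per library and the 5 highest Fano factors per library. Ribosomal cluster genes and others named outside this rule are said to be chosen after their values were seen.

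The 26 gene lists, also fixed before the data were examined, were matched on symbols only. They were heat shock and protein quality control, cold shock and RNA helicases, oxidative stress and thiol redox, general stress and hibernation, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, transcription machinery, glycolysis and lactate formation, lactose and sugar uptake, proteolysis and peptide uptake, the proton-translocating ATPase, cell wall synthesis, cell division and chromosome segregation, fatty acid and membrane lipid synthesis, DNA repair and recombination, DNA replication and topology, purine and pyrimidine synthesis, osmolyte, potassium and polyamine transport, exopolysaccharide synthesis, protein export, transposases, prophage and restriction-modification, CRISPR-associated genes, toxin-antitoxin genes and structural RNAs. Transposases, prophage and restriction-modification, and toxin-antitoxin genes matched no feature, and structural RNAs are reported as shares of all counts. Matching ignored case, so a gene spelled *Asns* entered the aminoacyl-tRNA synthetases, and *rps1* counted as a ribosomal protein gene. A list's median log2 ratio was placed among 10000 random lists of its size matched on deciles of mean expression, and stood apart below percentile 2.5 or above 97.5. Lists with fewer than 3 measured genes were not ranked.

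For variation between cells, each cell was thinned without replacement to 20 mRNA counts, the lower quartile of FD (22) rounded down to a multiple of 10, and shallower cells were left out. Fano factors were computed on 3056 cells of each library for genes with a mean of at least 0.02 counts per thinned cell. A squared CV, the excess of a gene's variance over cells above counting noise divided by its squared mean, was computed on unthinned cells with at least 20 mRNA counts for genes with at least 1000 counts, and gives deep cells more weight. Covariation of a list was set against 200 random lists matched on expression. Clusters were made per library and jointly on cells with at least 20 mRNA counts: log counts scaled per cell, 300 variable genes by Pearson residuals, 10 principal components, 15 neighbours and Leiden clustering at resolution 0.5. In a further test each count was put at random in 1 of 2 equal parts, clusters came from the first part, and genes with at least 100 counts in the second were compared there, with membership shuffled 20 times. Clusters keep numbers only, since no cell type markers were fixed for this strain.

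Before use, the fold rule, intervals, squared CV, Fano factor and list percentile were tested on simulated data; list covariation and the operon test were not. The fold rule was run with 200 genes changed 3- or 4-fold. Changes were recovered for 100% of the changed genes measured in every comparison and direction, except 96.0% of the 3-fold lower genes in FD2w against FD. Of unchanged genes, 0 of 1044 passed in FD against CT, 11 of 1577 in FD2w against FD and 3 of 1590 in FD2w against CT. Intervals held the true ratio in 96.4%, 95.3% and 95.4% of genes. For genes simulated with a squared CV of 1 the median estimates were 0.985, 0.889 and 0.936 in CT, FD and FD2w, and for a value of 0 they were −0.00, 0.01 and −0.00. No gene reached a Fano factor of 1.2 in simulated identical cells. Of 100 random lists, 2 lay outside the central range, in noise drawn independently for each gene. Alternatives covered the scaling, the features in the total, the count minimum, the cells used, the weighting of cells, the fold, the depth and the matrix record, with cells of at least 100 mRNA counts and the nc features added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.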

Results

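Single-cell RNA sequencing was carried out on the yogurt starter bacterium *Lactobacillus delbrueckii* subsp. *bulgaricus*, strain sp1.1, at 3 points of its preparation as a dried powder. The culture (CT) was grown for 12 h at 37 °C in MRS broth, a rich medium for lactobacilli, from a 2% inoculum. For the freeze-dried powder (FD), washed cells were mixed with 30% maltodextrin, a starch-derived protectant, held at −80 °C for 24 h and dried at −60 °C for 48 h. The stored powder (FD2w) was kept under vacuum at 4 °C for a further 2 weeks. Each group was 1 library, so differences between groups have no replicate check and no p-value is given. Intervals are 95% intervals, and those of CPM and ratios cover counting error only. Those of medians per barcode and shares of cells cover sampling of barcodes within a library. Those of shares of operons cover sampling of operons. None covers variation between libraries of the same group.

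The CT library held 3535 cell barcodes and 2936289 counts, the FD library 3805 barcodes and 2026425 counts, and the FD2w library 17002 barcodes and 4173127 counts. The median count per barcode was 751 in CT (744 to 760), 395 in FD (386 to 403) and 206 in FD2w (205 to 208). The FD and FD2w matrices were recorded under each other's sample and were assigned by the sizes of the barcode and feature lists they fit. Counts on gene45 to gene48, treated here as ribosomal RNA, made up 84.0% of CT and 90.0% of FD counts but 0.00901% of FD2w counts, whose table has separate ribosomal RNA features with 17.3% of counts. Whether FD2w was processed or annotated differently is not stated, so every ratio with FD2w includes any such difference. That left 468749 mRNA counts in CT, 202529 in FD and 3322072 in FD2w, or a median of 134, 34 and 167 mRNA counts per barcode. Expression is given below as CPM, counts per 1000000 mRNA counts on the 2021 other genes that the 3 tables share.

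In the culture, mRNA was concentrated on a few genes. The chaperonin gene *groL* (gene1493) had 101709 CPM (100798 to 102626) and *gap* (gene581), glyceraldehyde phosphate dehydrogenase of glycolysis, had 93570 CPM. They were followed by the elongation factor gene *tuf* (gene722, 31317 CPM), the lactate dehydrogenase gene *ldhA* (gene90, 26313 CPM) and the chaperone gene *dnaK* (gene1206, 19467 CPM). The 10 highest genes held 34.2% of mRNA counts in CT, 8.06% in FD and 33.8% in FD2w. An entropy-based effective number of genes was 240 in CT, 1152 in FD and 242 in FD2w. The highest genes in FD were again *gap* (28055 CPM), *groL* (11628 CPM) and *tuf* (8626 CPM), then *eno* (gene1186, enolase, 6152 CPM) and *pgk* (gene582, phosphoglycerate kinase, 5214 CPM). In FD2w *gap* reached 86818 CPM, *groL* 86219 CPM and *tuf* 39990 CPM, followed by *nrdD* (gene195, anaerobic ribonucleotide reductase, 23097 CPM) and the unnamed gene1622 (21175 CPM).

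**Figure D1:**
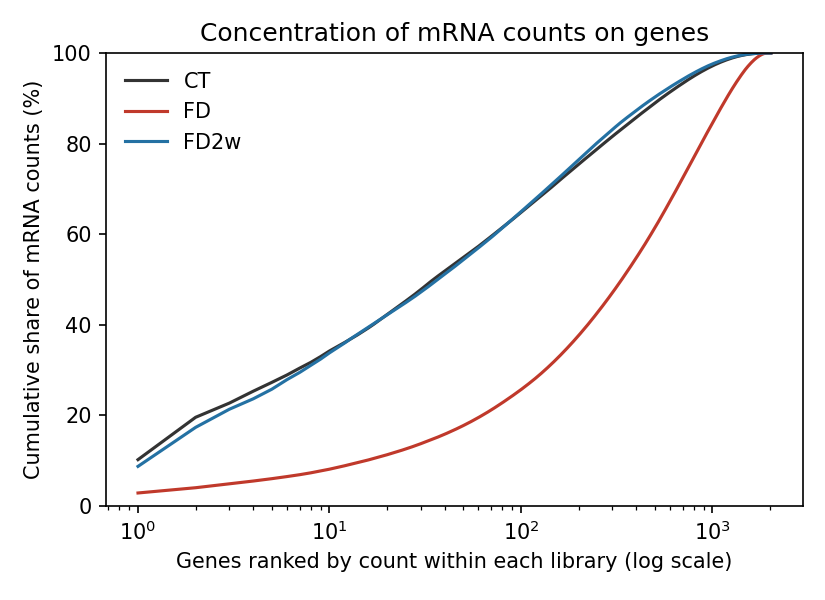
Cumulative share of mRNA counts (%) against genes ranked by count within each library (log axis), for CT, FD and FD2w. The top 10 genes hold 34.2% of counts in CT and 33.8% in FD2w but 8.06% in FD.

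The comparison of FD with CT asks how the transcript profile of the freeze-dried powder differed from that of the fresh culture. Chaperone genes, among the most abundant transcripts of the culture, made up a much smaller part of the profile after drying. *groL* was at 0.114 times its CT level (0.110 to 0.119), its partner *groS* (gene1494) at 0.206 times (0.180 to 0.234), *dnaK* at 0.188 times (0.174 to 0.203), *gap* at 0.300 times and *ldhA* at 0.176 times. Several genes of DNA repair, with few counts in the culture, made up a larger part, among them *recX* (gene513, 12.2-fold, 7.87 to 19.8), *mutS2* (gene102, 10.1-fold, 6.92 to 15) and the helicase gene *recQ* (gene760, 8.08-fold, 5.89 to 11.3).

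Of 1132 genes with at least 100 counts over FD and CT, 602 were at least 2-fold higher in FD with a counting interval excluding 1, 97 were at 0.5 times or lower, and 433 lay between. Of these, 112 of the higher and 19 of the lower genes have no symbol. The split depended on the scaling and on the count minimum. Median-of-ratios size factors shifted all log2 ratios by −1.40, leaving 242 genes higher and 361 lower, and ribosomal RNA kept in the total gave 387 and 211, so ratios are relative to the chosen total. With only cells of at least 100 mRNA counts, an alternative added after seeing the data, 263 were higher and 83 lower. Of the 225 genes with at least 500 counts, 21 were higher and 74 lower, so the balance turned among the most counted genes.

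Among the lowest genes in FD, besides *groL*, *dnaK*, *groS* and *ldhA*, were the ribosomal protein genes *rpmE2* (gene319, 0.116 times, 0.0820 to 0.159) and *rps1* (gene795, 0.234 times), and *copB* (gene1137, named for a copper-transporting ATPase, 0.120 times, 0.108 to 0.132). The thioredoxin gene *trxA* (gene1478) was at 0.209 times, the glutamine transport gene *glnP* (gene473) at 0.216 times, *rnpA* (gene2024, the protein of RNase P) at 0.224 times, *engB* (gene725) at 0.226 times and *pacS* (gene604) at 0.233 times. The highest ratios were those of genes with 5 to 20 counts in CT, so their intervals are wide. *potH* (gene1988, named for polyamine transport) was 56.0-fold higher (23.4 to 176), *urdA* (gene118) 44.3-fold (26.4 to 80.2), *ganQ* (gene179, sugar transport) 42.1-fold and *apu* (gene1635) 37.4-fold. *pyrD* (gene1939, pyrimidine synthesis) was 37.0-fold higher, *yjjB* (gene1849) 30.6-fold and *agrA* (gene21) 29.2-fold. Copies of *dppA* (gene973, 45.3-fold; gene391, 41-fold; gene190, 29.2-fold) and *Slc16a12* (gene1640, 55.5-fold; gene1642, 39.8-fold) were also in this group, but each symbol is on several genes and their counts are uncertain if reads were shared between copies.

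Gene lists fixed beforehand were set against 10000 random lists matched on expression. The heat shock and protein quality control list stood below the random lists in FD against CT: of 17 measured members 10 were lower, 5 higher and 2 between, with a median log2 ratio of −1.50 at percentile 0.0650. Its exceptions included the disaggregase gene *clpB* (gene345), 6.66-fold higher (5.0 to 8.97). General stress and hibernation also stood below, although none of its 4 measured members reached the 2-fold rule (median −0.54, percentile 1.25). Its members included *hpf* (gene554, ribosome hibernation) at 0.663 times and *relA* (gene825) at 1.87 times. DNA repair and recombination stood above, with 19 of 32 higher, 1 lower and a median of 1.51 (percentile 99.3). With a minimum of 500 counts none of these 3 stood apart, as given among the alternatives below.

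The other 18 ranked lists lay within the random range in FD against CT. In purine and pyrimidine synthesis 22 of 33 genes were higher and 1 lower (median 1.67), with *carA* (gene1935) 16.1-fold and *pyrC* (gene1936) 14.0-fold higher. In cell division and chromosome segregation 10 of 13 were higher and none lower (1.28), including *noc* (gene1877, 7.37-fold), *mnmG* (gene2021, 6.74-fold) and *smc* (gene1271, 5.62-fold). DNA replication and topology had 13 of 21 higher and 1 lower (1.25; *topB*, gene1342, 16.5-fold), cell wall synthesis 13 of 31 higher and 1 lower (0.81; *pbp2a*, gene1425, 14.5-fold), and fatty acid and membrane lipid synthesis 11 of 18 higher and 1 lower (1.14; *cls*, gene161, cardiolipin synthase, 6.50-fold). Proteolysis and peptide uptake had 14 of 37 higher and 3 lower (0.49), protein export 5 of 9 and 1 (1.12), exopolysaccharide synthesis 2 of 4 and 0 (1.57), and oxidative stress and thiol redox 4 of 8 and 3 (0.95).

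Lists of growth functions were mixed in the same comparison, in which the median log2 ratio of all measured genes was 1.11. Ribosomal proteins had 11 of 45 genes higher and 12 lower (0.15). Glycolysis and lactate formation had 4 of 18 higher and 6 lower (−0.24), with *gpmA* (gene1608, phosphoglycerate mutase) 18.4-fold higher beside the low *ldhA*. Lactose and sugar uptake had 3 of 9 higher and 5 lower (−1.07), with the phosphocarrier gene *ptsH* (gene525) at 0.253 times and *fruK* (gene1864) 7.55-fold higher. Of the proton-translocating ATPase genes 1 of 8 was lower and none higher (−0.81; *atpB*, gene650, 0.417 times). Translation factors had 2 of 16 higher and 2 lower (−0.16), with *tuf* at 0.275 times. Aminoacyl-tRNA synthetases had 6 of 23 higher and 1 lower (0.41), transcription machinery 4 of 14 and 1 (0.24), osmolyte, potassium and polyamine transport 2 of 6 and 0 (0.05; *opuCC*, gene1087, 16.8-fold), and cold shock and RNA helicases 0 of 3 and 0 (0.04). Both measured CRISPR-associated genes were higher, *cas1* (gene816) 21.0-fold and *cas9-2* (gene815) 3.50-fold. With size factors, of the medians above 0 only those of DNA repair (0.11), purine and pyrimidine synthesis (0.27) and exopolysaccharide synthesis (0.16) stayed above 0; percentiles compare lists under one scaling.

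**Figure D2:**
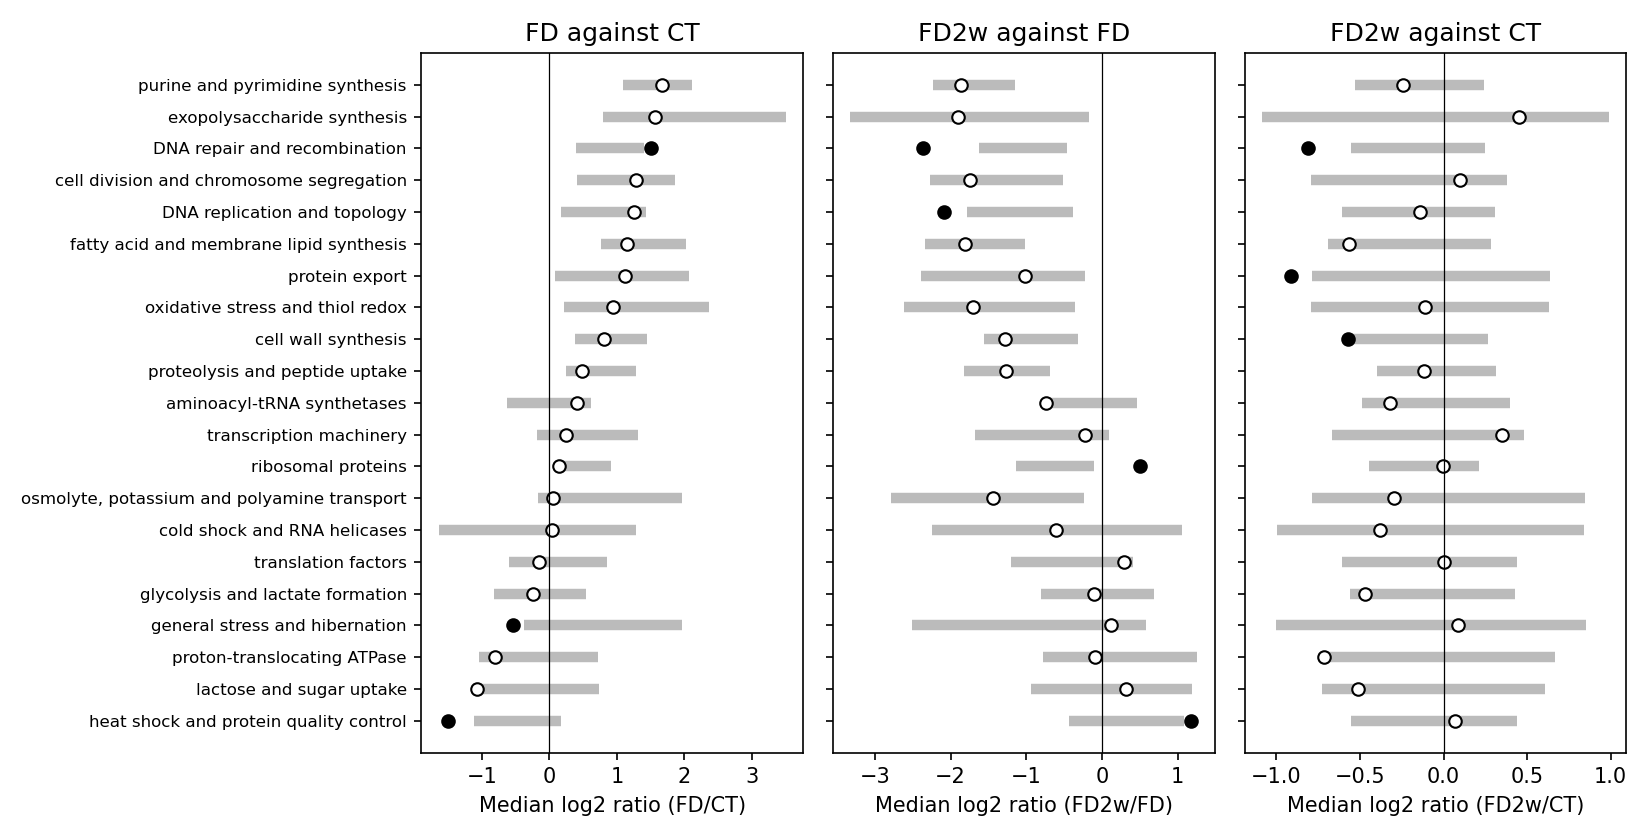
Median log2 ratio of CPM for the 21 ranked gene lists in each comparison (points), with the 95% range of medians of random lists matched on expression (grey bars). Filled points lie outside that range: heat shock is at −1.50 in FD against CT and 1.18 in FD2w against FD.

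The comparison of FD2w with FD asks what differed in the powder after 2 weeks of cold storage. The most abundant transcripts of the culture again made up a larger part of the profile in the stored powder than in FD. *groL* was 7.41-fold higher in FD2w than in FD (7.12 to 7.72), *dnaK* 4.28-fold (3.98 to 4.60), *tuf* 4.64-fold (4.42 to 4.86) and *gap* 3.09-fold. Most DNA repair genes were lower (25 of 34 measured, with the other 9 not past the 2-fold rule). Some were far lower, with *recN* (gene1309) at 0.0348 times (0.0279 to 0.0433), *recQ* at 0.0476 times and *recG* (gene272) at 0.0530 times. DNA replication genes such as *polC* (gene1231, a replicative polymerase) were at 0.110 times (0.0980 to 0.123) and *dnaE* (gene780) at 0.114 times.

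Of 1538 genes measured, 128 were at least 2-fold higher in FD2w than in FD, 941 were at 0.5 times or lower, and 469 lay between; 33 of the higher and 234 of the lower have no symbol. Size factors shifted log2 ratios by 1.56 and gave 469 higher and 414 lower, and ribosomal and transfer RNA kept in the total gave 953 and 139. After *secE* (gene1544, protein export), whose 13.5-fold ratio (3.71 to 112) rests on 2 counts in FD, the highest named genes were *copB* (10.8-fold, 9.78 to 11.9), *rpmE2* (7.78-fold), the protease gene *clpP* (gene572, 7.50-fold) and *groL*. They were followed by *rpoE* (gene316, a subunit of RNA polymerase, 6.51-fold), the cold shock gene *cspL* (gene1941, 6.29-fold, 4.47 to 9.16), *steT* (gene229, 6.28-fold), *glnP* (6.22-fold), *rplM* (gene387, ribosomal protein, 5.85-fold), *nrdD* (5.65-fold) and *glnQ* (gene470, 5.46-fold). The lowest were *dppA* (gene973, 0.00688 times), *MIMI-R475* (gene864, 0.00822 times), *yhcF* (gene1562, 0.00941 times) and the peptidase gene *pepT* (gene335, 0.00992 times). The rest of the 12 lowest, *ycaM* (gene501), *kgtP* (gene457), *pedD* (gene99), *ramC* (gene25), *chbR* (gene1406), *cas1*, *urdA* and *endA* (gene1807), lay between 0.0129 and 0.0182 times.

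In FD2w against FD, 4 gene lists stood apart. Heat shock stood above (10 of 17 higher, 5 lower, median 1.18, percentile 98.7), with *hslO* (gene332) an exception at 0.138 times. At a minimum of 500 counts heat shock lay within the random range (percentile 94.6). Ribosomal proteins also stood above, with a median of 0.50 at percentile 100, although 16 of 47 were higher and 14 lower; *rpmE2* was 7.78-fold higher while *rplF* (gene371) was at 0.0980 times and *rplO* (gene375) at 0.140 times. DNA repair (25 of 34 lower, none higher, median −2.36) lay below all random lists, at percentile 0, and DNA replication and topology (16 of 24 lower, 2 higher, −2.09) was at percentile 0.240. Some genes of these lists, such as *polC* and *rplF*, come late in operons, along which ratios of FD2w to FD also fell, as given at the end. For this comparison the lists were not ranked without such genes.

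Within the random range, cell division and chromosome segregation had 13 of 15 genes lower and none higher in FD2w than in FD (−1.75), purine and pyrimidine synthesis 30 of 42 and none (−1.86; *purF*, gene1329, 0.0229 times), and fatty acid and membrane lipid synthesis 17 of 24 lower and 1 higher (−1.80; *accA*, gene846, 0.0409 times). Cell wall synthesis had 19 of 32 lower and 2 higher (−1.28; *dapF*, gene1010, 0.0298 times), proteolysis and peptide uptake 27 of 49 and 1 (−1.27), osmolyte transport 6 of 9 and 1 (−1.44), exopolysaccharide synthesis 2 of 4 and 0 (−1.91), and protein export 5 of 10 and 1 (−1.02; *ftsY*, gene1270, 0.0681 times). Oxidative stress and thiol redox had 6 of 10 lower and 3 higher (−1.70), with the iron-sulfur assembly gene *sufB* (gene1676) at 0.0361 times and *trxA* 5.22-fold higher. Aminoacyl-tRNA synthetases had 11 of 24 lower and none higher (−0.74; *leuS*, gene1451, 0.107 times), and transcription machinery 4 of 15 and 2 (−0.23).

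Other lists had about as many genes higher as lower by CPM in FD2w against FD. The median log2 ratio of all 1538 measured genes was −1.49. With size factors the medians of the lists below ranged from 0.95 (cold shock) to 1.87 (sugar uptake), so their balance depends on the scaling. Glycolysis had 4 of 19 genes higher and 6 lower (−0.10), sugar uptake 2 of 9 and 3 (0.31), translation factors 4 of 17 and 4 (0.29), and the ATPase 1 of 8 and 0 (−0.09; *atpB* 3.05-fold). Cold shock had 1 of 5 higher and 2 lower (−0.61), and general stress 1 of 5 and 1 (0.12), the higher gene being *hpf* (2.21-fold, 1.79 to 2.77). Both CRISPR-associated genes were lower, *cas1* at 0.0170 times and *cas9-2* at 0.180 times. With size factors, of the medians below 0 only those of DNA repair (−0.80), DNA replication (−0.53), exopolysaccharide synthesis (−0.35), purine and pyrimidine synthesis (−0.30), lipid synthesis (−0.25), cell division (−0.19) and oxidative stress (−0.14) stayed below 0.

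The comparison of FD2w with CT asks how far the stored powder differed from the starting culture. Of the 20 genes highest in CT, 18 lay between 0.5 and 2 times their CT level in FD2w, a tally made after the values were seen. The others were the unnamed gene1457, at 0.0144 times, and gene632, at 0.143 times. *groL* was at 0.848 times its CT level (0.840 to 0.856), *gap* at 0.928 times (above 1 with size factors) and *dnaK* at 0.804 times, while *tuf* was 1.28-fold higher and *nrdD* 1.81-fold. Among the genes with the highest ratios to CT were *glpF4* (gene59, a glycerol channel family member, 19.1-fold, 14.6 to 25.5), *lytG* (gene207, named for a peptidoglycan hydrolase, 13.4-fold, 11.3 to 15.9), *tagU* (gene213, named for teichoic acid attachment, 10.5-fold, 8.52 to 13.1) and *glmS* (gene449, the first enzyme of amino sugar synthesis, 10.3-fold, 8.85 to 12.1). *cspL* was 8.15-fold higher (6.30 to 10.7), and the DNA repair gene *recN* was at 0.207 times (0.157 to 0.274).

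Of 1402 genes measured in FD2w and CT, 213 were higher, 231 lower and 958 between; 79 of the higher and 45 of the lower have no symbol. Size factors shifted log2 ratios by 0.16 and gave 258 higher and 171 lower, while ribosomal and transfer RNA kept in the total gave 1284 and 6. Across 1570 genes, which are not independent replicates, log2 CPM correlated at r = 0.83 between FD2w and CT, 0.62 between FD and CT and 0.49 between FD2w and FD. The highest ratio was that of *pstS* (gene873, phosphate binding, 25.2-fold, 11.6 to 68.9), followed by *pyrB* (gene954, 20.0-fold, 9.15 to 54.6), both with 6 counts in CT. Other high genes were *ytsP* (gene344, 13.1-fold), *lysA* (gene30, lysine synthesis, 11.5-fold), *dppA* (gene865, 11.4-fold, a multi-copy name), *pyrD* (10.4-fold), *met17* (gene341, 10.2-fold) and *yfiB* (gene1059, 9.52-fold). The lowest were *fabZ* (gene843, fatty acid synthesis, 0.0864 times, 0.0674 to 0.110), *pepIP* (gene1724, 0.0954 times), *dapA* (gene1014, diaminopimelate synthesis, 0.109 times), *scpB* (gene790, chromosome condensation, 0.113 times), *SPAC17G8.11c* (gene411, 0.115 times) and *endA* (0.118 times). They were followed by *cadA* (gene434, 0.133 times), *carA* (gene937, 0.139 times), *cmkA* (gene1983, 0.145 times), *ftsK* (gene542, 0.149 times), *comEC* (gene716, 0.156 times) and *aspS* (gene829, 0.156 times).

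Cell wall synthesis, DNA repair and protein export stood below the random lists in FD2w against CT. In cell wall synthesis 10 of 31 genes were lower and 2 higher (median −0.57, percentile 1.96), with *dapA* and *dapB* (gene1015, 0.294 times) low and *glmS* high. In DNA repair 13 of 34 were lower and 1 higher (−0.81, percentile 0.050), including *dinB* (gene1486, 0.268 times) and *xseA* (gene1313, 0.328 times). In protein export 4 of 10 were lower and none higher (−0.92, percentile 0.920), with the translocase gene *secY* (gene376) at 0.308 times, *ftsY* at 0.416 times and *yidC* (gene2023) at 0.443 times. Some of these genes come late in operons, along which ratios of FD2w to CT fell, as described at the end. Without the genes after the first of each listed operon, an alternative added after seeing the data, protein export (−0.51, percentile 14.4) and cell wall synthesis (−0.39, percentile 10.5) no longer stood apart, while DNA repair did (−0.81, percentile 0.0400). This step removed only 4 of the 34 DNA repair genes, and 2 of its 13 lower ones. It removed 7 of 31 genes in cell wall synthesis and 2 of 10 in protein export. Genes of unlisted operons stayed in, so the step hardly tests operon position for DNA repair. At a minimum of 500 counts protein export and cell wall synthesis also lay within the range. In each comparison 21 lists were ranked, of which 1.05 would lie outside by chance if list members varied independently. Some lists hold neighbours from operons: 23 of 47 ribosomal protein genes and 7 of 8 ATPase genes come after the first gene of a listed operon. For such lists that number is no firm guide.

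The chaperone list lay within the random range in FD2w against CT, with 1 of 17 genes higher (*clpB*, 2.80-fold), 1 lower (*dnaJ*, gene1205, 0.441 times) and a median of 0.07. Glycolysis had 0 of 19 higher and 0 lower (−0.47; *ldhA* 0.518 times), translation factors 1 of 17 and 0 (0.01; *infA*, gene378, 2.21-fold), and sugar uptake 0 of 9 and 1 (−0.51; *manZ*, gene1659, 0.458 times). The ATPase had 0 of 8 higher and 3 lower (−0.71): *atpG* (gene655, 0.341 times), *atpD* (gene656, 0.387 times) and *atpC* (gene657, 0.402 times). Transcription machinery had 2 of 15 higher, *rpoE* (4.26-fold) and *rpoY* (gene707, 2.63-fold), and 1 lower, *rpoC* (gene349, 0.222 times; median 0.35). DNA replication had 1 of 24 higher and 6 lower (−0.14), purine and pyrimidine synthesis 8 of 35 and 5 (−0.24), lipid synthesis 1 of 22 and 7 (−0.57), and cell division 0 of 14 and 3 (0.10).

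Proteolysis and peptide uptake had 8 of 44 genes higher and 4 lower (−0.12), aminoacyl-tRNA synthetases 2 of 24 and 5 (−0.32; *glyQ*, gene1146, 3.14-fold), osmolyte transport 2 of 9 and 4 (−0.30) and exopolysaccharide synthesis 0 of 4 and 1 (0.45). Oxidative stress had 1 of 10 higher and 3 lower (−0.11), the lower ones being *sufB* (0.202 times), *sufD* (gene1679, 0.226 times) and *sufC* (gene1680, 0.276 times). Cold shock had 1 of 5 higher and 1 lower (−0.38), general stress 0 of 5 and 1 (0.09), and the single measured CRISPR-associated gene, *cas9-2*, was at 0.628 times. Ribosomal proteins had 10 of 47 higher and 8 lower (−0.00), and their medians, with those of oxidative stress, proteolysis and DNA replication, were above 0 with size factors. Their spread followed gene order in the main ribosomal protein cluster, an observation made after the values were seen: *rplD* (gene358) was 4.16-fold and *rplW* (gene359) 4.62-fold higher near its start, and *rplF* was at 0.225 times further along.

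**Figure D3:**
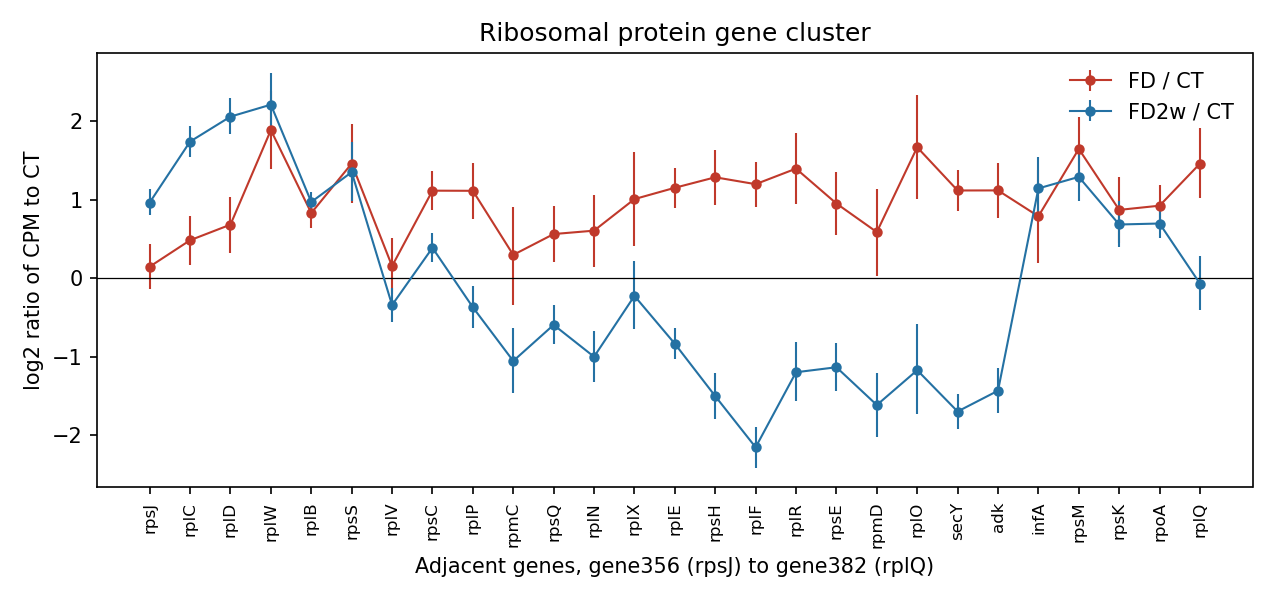
Log2 ratio of CPM to CT for adjacent genes of the ribosomal protein cluster, in feature order, in FD (red) and FD2w (blue); bars are 95% counting intervals. FD2w runs from 4.62-fold at *rplW* to 0.225 times at *rplF*, then back to 2.21-fold at *infA*.

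Many genes differed in one direction between CT and FD and in the other between FD and FD2w. Of 1130 genes measured in both comparisons, 601 were higher in FD than CT and 649 lower in FD2w than FD, and 529 were both, against 345 for independent lists. Another 62 were lower in FD than CT and higher in FD2w than FD, from 97 and 113 genes, against 9.70 for independent lists. Both comparisons share the FD library, which could not be split into replicates. With no effects, simulated sharing gave 0.01 and 0.05 genes. The simulation drew all libraries from a single pooled profile, so hardly any gene could pass. Neither it nor the independent lists give a baseline for a departure of the FD library alone, which would appear as the same reversal. The log2 ratios correlated at −0.82 (simulated −0.81 with no effect), with a covariance of −2.54 (simulated −0.03).

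The title of the series concerns heterogeneity within the population, so variation between cells was measured in each library. Cells of FD spread their counts more evenly over genes than cells of CT and FD2w did. With each cell thinned to 20 mRNA counts, the median number of genes per cell was 17 in CT, 19 in FD and 17 in FD2w, with 145, 749 and 0 shallower cells left out; without thinning it was 80, 31 and 90. At 40 counts it was 30, 36 and 30, with 389, 2177 and 6 cells left out. The 100 genes highest in CT held 64.8% of CT mRNA counts, 21.4% in FD and 59.9% in FD2w. Over cells with at least 20 mRNA counts the median share was 65.0% in CT (5th to 95th percentile 56.2 to 75.8), 17.4% in FD (5.88 to 38.7) and 60.3% in FD2w (51.0 to 68.9). The SD of this share over cells was 6.04, 10.1 and 5.59 percentage points, against 4.82, 6.51 and 3.80 from binomial sampling alone.

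**Figure D4:**
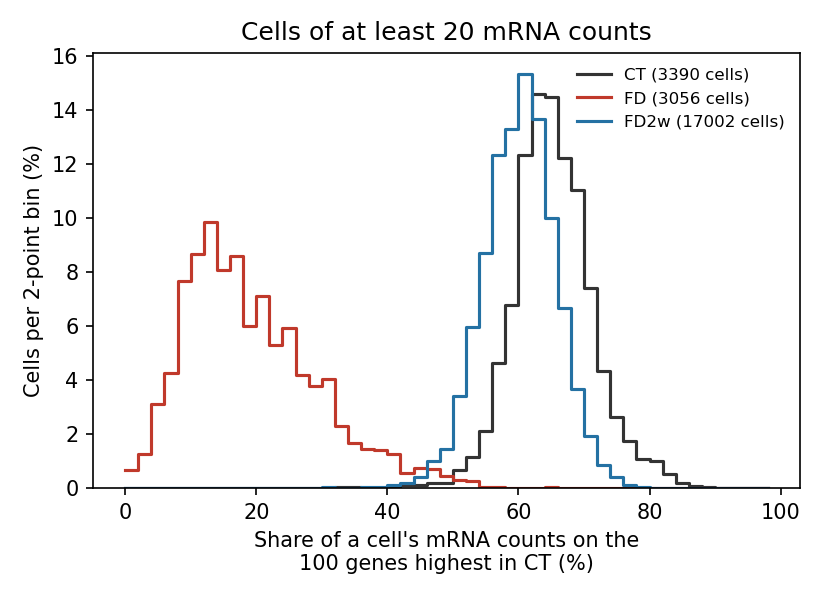
Distribution over cells with at least 20 mRNA counts of the share of a cell's mRNA counts (%) on the 100 genes highest in CT, as percent of cells per 2-point bin. The medians are 65.0% in CT, 17.4% in FD and 60.3% in FD2w.

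Fano factors stayed near 1 in cells thinned to 20 counts, where most genes had so few counts that even strong variation between cells hardly raises them. On 3056 cells of each library thinned to 20 counts, a Fano factor (variance over mean) of at least 1.5 was found for 0 of 153 genes in CT, 1 of 229 in FD and 0 of 170 in FD2w, with medians of 1.02, 1.07 and 1.03. The FD gene was *SBSN* (gene1793), with 1.61. Next in FD were the unnamed gene1622 (1.48) and gene1369 (1.35), then *lytG* (1.23) and *gap* (1.23). The highest in CT were *clpC* (gene1929, a chaperone ATPase, 1.27), gene632 (1.17), *pta* (gene588, 1.16), gene250 (1.14) and *recF* (gene4, 1.12). In FD2w they were *fusA* (gene355, elongation factor, 1.18), *atpD* (1.15), *kup* (gene202, potassium uptake, 1.15), *clpC* (1.14) and gene171 (1.14).

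Variation between cells showed in a squared CV with counting noise removed, computed without thinning on genes with at least 1000 counts, which averages near 0 for cells with the same profile. Over the 66 such genes of both CT and FD2w its median was 0.302 in CT and 0.489 in FD2w, and 55 of them were higher in FD2w. Over the 5 genes of all 3 libraries it was 0.102 in CT, 2.47 in FD and 0.114 in FD2w, but 0.925 in FD without the 5% of cells with the most counts, an alternative added after seeing the data. If identifiers were not collapsed, repeated reads of a molecule add to these values.

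Genes of some lists varied together over cells, measured as the variance of a list's summed counts over the sum of its members' variances. In FD the ratio was 1.19 for glycolysis (random lists 0.933 to 1.03), 1.06 for ribosomal proteins and 1.04 for heat shock, the 3 of 17 lists outside the random range. In CT, heat shock (0.857, random 0.908 to 1.02) and glycolysis (0.908) lay below and the ATPase (1.03) above, of 13 lists. All thinned cells have 20 counts, so a list holding many of them gets a ratio below 1 without covariation. Heat shock held 3.31 and glycolysis 3.75 counts per thinned CT cell. Random lists were matched on deciles of expression, not on that sum, so both low values cannot be read as opposed variation. In FD2w the ATPase (1.06) and proteolysis (1.03) lay above and transcription machinery (0.951) below, of 13 lists. By chance 0.650, 0.850 and 0.650 lists would lie outside in CT, FD and FD2w. Of these 9 lists, the FD lists and the ATPase in CT also lay outside on the same side both at 40 counts and without the 5% of cells with the most counts. Lactose and sugar uptake in FD, within the range at 20 counts, lay above in both (1.06 and 1.04). None of the 3 FD2w lists did so in either setting, where ribosomal proteins lay above in FD2w (1.05 and 0.994).

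Clustering gave a few groups of cells in each library, and some of them differed in more genes than with shuffled membership. At resolution 0.5 the cells formed 4 clusters in CT, 5 in FD and 5 in FD2w, the largest holding 31.5%, 35.1% and 30.7% of cells. Simulated identical cells with the same depths and mean profile formed 5, 7 and 22 clusters, with a modularity of 0.517, 0.573 and 0.843, against 0.490, 0.520 and 0.555 for the real cells, so neither number shows distinct groups by itself. In a test chosen after seeing the data, the counts of each cell were split at random in 2 equal parts, and clusters made on the first part were compared with the remaining cells on the second. In FD a cluster of 496 cells differed by the 2-fold rule in 65 of 207 genes, against at most 5 in 20 shuffles of its membership, and in FD2w one of 2016 cells differed in 31 of 1105 genes (at most 10). In all, 1 of 5 clusters in CT, 4 of 9 in FD and 1 of 4 in FD2w differed in more genes than in any shuffle, against 0 of 7, 1 of 11 and 2 of 27 in simulated identical cells. The 496 FD cells were deep, with 24142 counts in the second part against 13790 in the next cluster of 491 cells. Shuffles did not match depth, though the simulated cells did. If identifiers were not collapsed, repeated reads of a molecule can fall in both parts, which would then not be independent. On whole counts FD2w also had a cluster of 389 cells (2.29%) with *carB* (gene938) 12.4-fold, *secY* 11.4-fold and *rpoC* 7.27-fold higher than in its other cells, folds raised by the choice of genes. The 3 libraries together formed 78 clusters, 24 of them with at least 1% of cells. In FD, cluster 3, with 21.5% of cells, had 36.1% of its mRNA counts on the 100 genes highest in CT, against 14.8% to 17.8% in the others. Clustered without those 100 genes, the highest cluster still had 28.6%, against 16.1% to 18.9% in the others.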

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

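All tests in this part were chosen after the results were seen. Structural RNA stood out because it lies outside the mRNA counts compared above and far exceeds the limit that a count of 0 allows. Features gene45 to gene48 took 84.0% of all counts in CT and 90.0% in FD but 0.00901% in FD2w, where 376 counts remained. In FD2w the further features took 17.3% (rRNA), 0.904% (tRNA) and 2.20% (nc) of all counts. Of the nc features, nc.4 had 52726 counts, equal to 15871 per 1000000 mRNA counts, and nc.3 had 28299.

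The mRNA profile of FD was flat, with 1152 effective genes against 240 in CT. The tables argue against lower depth as the cause, because CT thinned to the FD total still had 238 effective genes. An even background added to culture-like RNA could not be the whole cause: after taking away the largest culture-like part the counts allow (11.4%), the 100 genes highest in CT held 15.8% of the rest, against an even share of 4.95% by number of genes. Ratios of FD to CT among the 20 highest CT genes also ranged from 0.114 for *groL* to 0.647 for *pgk*, the first test tried. Barcodes that kept the full culture profile, mixed with flat ones, are argued against as more than a small part. The 95th percentile of the share on those 100 genes over FD cells was 38.7%, below the 5th percentile over CT cells of 56.2%. A mixture with barcodes that kept part of that profile stays open. The SD of the share over FD cells was 10.1 percentage points, against 6.51 from binomial sampling. An FD cluster held 36.1%, against 14.8% to 17.8% in the others, when those 100 genes were allowed in the clustering. Clustered without them, the highest cluster held 28.6%, against 16.1% to 18.9% in the others. Also open are uneven loss of RNA during drying, a background that is itself uneven, or both, and freeze-drying as a biological cause. None of these was tested.

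FD2w lay nearer to CT (r = 0.83 over genes) than FD did (r = 0.62). Another annotation of FD2w, whose table has further features, cannot be told apart from an effect of storage, because the 0.83 over shared genes is the pattern itself. Another processing of the FD2w library, such as removal of ribosomal RNA, also stays open: ribosomal RNA took 17.3% of its counts against 84.0% and 90.0% in CT and FD, and this would bear on every ratio with FD2w. An exchange of the FD and FD2w libraries before deposit cannot be told apart from an effect of storage. The labels give no marker that differs between fresh and stored powder, the matrix records were crossed, and with the exchange the 0.62 would belong to the stored powder. Storage itself stays open as a biological cause, untested without replicates.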

How the results depend on the processing

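No paired analysis was possible because each group is 1 library, and none could be left out. Of the named genes past the 2-fold rule, 3 changed direction over the scaling by size factors and the alternatives of cells, weights and depth. Those not past it changed sides of 1 in 9 of 168 values, for example *gap* in FD2w against CT with size factors. With median-of-ratios scaling, *sigA* (gene1141) was at 0.924 times in FD against CT (2.44 with CPM), *potD* (gene595) at 0.794 times (2.10) and *rnr1* (gene1691) at 1.41-fold in FD2w against FD (0.480), because that scaling shifts every ratio of a comparison alike. Counts of genes are given as higher and lower. That scaling gave 242 and 361 genes in FD against CT and 469 and 414 in FD2w against FD. With rRNA and tRNA in the total they were 387 and 211 in FD against CT, 953 and 139 in FD2w against FD, and 1284 and 6 in FD2w against CT, following the unequal rRNA shares. With that total, 356 of the 941 genes lower in FD2w against FD were called higher, as were 113 of the 231 lower in FD2w against CT. The tally of named genes above leaves that total out. A minimum of 20 counts gave 1137 and 100 in FD against CT. A minimum of 500 gave 21 and 74 there, so that most genes called were then lower. It gave 121 and 303 in FD2w against FD, and 131 and 83 in FD2w against CT, with fewer genes measured. At 1.5-fold, 165 were lower in FD against CT and 334 and 429 differed in FD2w against CT; at 3-fold, 45 were lower in FD against CT, 69 higher in FD2w against FD, and 109 and 71 in FD2w against CT. Thinning the libraries to the smallest mRNA total gave 527 lower in FD2w against FD and 85 and 79 in FD2w against CT, so depth limits these counts. Cells with at least 100 mRNA counts, an alternative chosen after seeing the data that keeps 2576, 395 and 16574 cells, gave 263 higher in FD against CT. With the nc features in the total, also added later, no count moved by over 1.5 times. Exchanging the FD and FD2w matrices gave 213 and 231 in FD against CT, 941 and 128 in FD2w against FD, and 602 and 97 in FD2w against CT, by construction. Cells with at least 20 mRNA counts and equal weights for cells moved no count of genes by over 1.5 times.

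Gene lists standing apart in FD against CT numbered 5 with a minimum of 20 counts, 1 with 500, 5 without the top 5% of cells and 5 with equal weights (3 as reported). With 500 none of the reported 3 was kept: heat shock was at percentile 3.02, DNA repair at 87.0 and general stress had too few measured genes, while ribosomal proteins stood below. Without the top 5% of cells general stress was at percentile 2.63. With 500, heat shock in FD2w against FD (percentile 94.6) and cell wall synthesis (20.0) and protein export (5.6) in FD2w against CT also lay within the range. In FD2w against CT the number was 5 with a minimum of 20, and 1 without later operon genes, an alternative added after seeing the data (3 as reported). No list median that stood apart changed sign in the settings run for lists. The total with rRNA and tRNA kept, which shifts all ratios of a comparison alike, was not among them. Median counts per cell without rRNA and tRNA were 134 in CT, 34 in FD and 167 in FD2w, so the order of libraries changes; without the top 5% of cells they were 741, 382 and 201, and in cells with at least 20 mRNA counts 445 in FD. Median genes per cell were 30, 36 and 30 thinned to 40 counts and 80, 31 and 90 not thinned, which reverses the place of FD, as depth per cell differs. Genes past the Fano threshold were 1 in CT and 6 in FD at 1.2, 0 in FD at 2, 3 in FD at 40 counts and 0 in FD with rRNA kept. Clusters numbered 1, 2 and 2 in CT, FD and FD2w at resolution 0.2 and 13, 12 and 17 at 1.0; the joint clusters fell from 78 to 6 with all genes of a mean of at least 0.02. Lists outside the random range of covariation, above or below it, numbered 5 in FD and 1 in FD2w at 40 counts, and 5 and 1 without the top 5% of cells (3 and 3 as reported). Glycolysis (1.48 and 1.13), ribosomal proteins (1.21 and 1.05) and heat shock (1.15 and 1.03) stayed above in FD. In CT at 40 counts heat shock and glycolysis no longer lay outside. The 3 FD2w lists were not among those outside in either setting, so they are not robust; the cause was not tested.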

Other observations

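The held-out operon test below was fixed before its differences were computed; all other tests in this part were chosen after the results were seen. Values of some held-out genes had been seen by then, and the pattern was noticed in the same libraries. The balance between the chaperone *groL* and the glycolytic *gap* differed within libraries, free of scaling: *groL* had 1.09 counts per *gap* count in CT (1.07 to 1.10), 0.414 in FD (0.395 to 0.435) and 0.993 in FD2w (0.988 to 0.998). For *dnaK* the ratio was 0.208, 0.130 and 0.180. Among unnamed genes chosen after their values were seen, gene749 was at 0 CPM in CT, 98.8 in FD and 6835 in FD2w, at least 1068-fold higher in FD2w than CT, and gene1842 at 111, 316 and 5374 CPM. In contrast gene1457 was at 9835, 1496 and 142 CPM, and gene1960 at 3765, 528 and 45.2 CPM.

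In FD2w, ratios to CT fell along operons, sets of adjacent genes transcribed together. The pattern was first seen in 8 operons, all of which had a lower ratio at the last gene than at the first (median log2 difference −1.60). In the ATPase operon *atpB* was at 1.27 and *atpC* at 0.402 times CT, *rpoB* (gene348) was at 1.52 and its neighbour *rpoC* at 0.222, and *rpsL* was at 2.69 and *fusA* at 0.881. In the main ribosomal cluster *rpsJ* was at 1.95 and *adk* at 0.370, after which *infA* (2.21) and *rpsM* (2.44) were high again. A list of 28 further operons was then written from textbook gene order, of which 21 had adjacent measured genes. The median difference there was −0.52, and 20 of 21 were below 0 (95.2%, exact binomial interval 76.2 to 99.9), the exception being the operon of *era* to *glyS* (0.63). The fall therefore also appears outside the operons in which it was noticed. It held in 19 of 21 without the 5% of cells with the most counts, in 19 with cells of at least 100 mRNA counts and in 16 with the libraries thinned to the smallest. Ratios of FD2w to FD fell too, in all 8 first operons (median −2.09) and in 16 of 21 held-out ones (−0.82).

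In FD against CT no fall common to the held-out operons was seen: 42.9% were below 0 (9 of 21, interval 21.8 to 66.0, median 0.14). Of the first 8 operons, 1 was below 0 in FD against CT (12.5%, interval 0.316 to 52.7, median 0.40), so the fall was not seen there either. The held-out interval still allows a fall in most operons, and each group is 1 library. Freeze-drying as such is therefore not excluded as the cause. Counting or annotation that differs in the FD2w table is argued against, because it would act on all FD2w cells alike. When FD2w cells were clustered on 370 genes outside the listed operons, a group of 424 cells (2.49%, 2.26 to 2.74) had an *rpoC* to *rpoB* ratio of 0.691 (0.608 to 0.784), against 0.107 (0.102 to 0.111) in the library, 0.730 in CT and 0.734 in FD. A candidate explanation is that much of the FD2w mRNA is recently begun transcripts whose 5′ parts are over-represented, for example from cells that resumed transcription before fixation; positions within genes, which would test it, are not used here, and an exchange of FD and FD2w would move the pattern to the other powder.

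The same 424 cells differed in other genes, given as values. In these cells *lytG* was at 621 CPM against 4017 in the whole library and 301 in CT, *glmS* at 1105 against 3590 and 348, *lysA* at 842 against 3525 and 307, and *tagU* at 516 against 2015 and 192. The unnamed gene1842 was at 684 CPM against 5374 and 111. In contrast gene749 was at 7030 CPM against 6835 and 0, and gene1457 at 52.6 CPM against 142 and 9835, so these cells did not have the culture's values for every gene. Over the 7 of the first 8 operons with enough counts there, the median difference was −0.06, against −1.51 to −1.73 in the other 4 clusters. The contrast was smaller over 20 held-out operons, with a median of −0.29 and 11 below 0, against −0.39 to −0.63 in the other clusters. Of those 20, 16 fell less in these cells than in the rest of FD2w (80.0%, exact binomial interval 56.3 to 94.3).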
